A study of Mus musculus with 8 samples.

How the data were processed

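Single cells were profiled from mouse oral carcinoma sites in 8 libraries. Per the labels' protocols, cultured carcinoma cells were made senescent with 600 nM paclitaxel for 48 h, 500000 cells were injected orthotopically per mouse, and the injection site was dissected on day 3 and dissociated with collagenase and dispase. In 1 group the senescent cells could release extracellular vesicles (EV-proficient) and in the other the release had been blocked genetically (EV-deficient). The labels do not name the gene that was altered. Per the titles, each group held tumours 1 to 3 as 3 separate libraries and tumours 4 to 6 as 1 pool marked with hashtag antibodies, so that 12 tumours were sampled. In the pools the library and the group cannot be told apart.

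The deposited matrices hold raw UMI counts per gene and barcode, already filtered to cell-containing barcodes by the authors. Per the submitters' processing notes, bcl2fastq 2.20.0.422, Cell Ranger 7.1.0 and STAR 2.7.2a were used with the GRCm38 mouse build; their settings are not given in the sources used here. Each deposited matrix lists 51913 gene features, and each pool also has 3 antibody features, counted by the authors as raw antibody counts. The deposited barcode and feature lists name the columns and rows of each matrix and hold no measurement. No column of values was left unused, and each library was checked against each other one: of 28 pairs of libraries 0 were identical, and the most alike pair (EV-deficient 1 and 2) differed far beyond sampling noise (chi-square per degree of freedom 11.4). Coordinates and gene types came from the GENCODE annotation of GRCm38, matched by gene ID for 77 of 77 named genes past a threshold.

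From the deposited counts, barcodes with at least 200 detected genes and at most 20% mitochondrial counts were kept. Doublets were sought per library with Scrublet and removed after clustering. The caller marked 0.249% to 1.28% of cells in the separate libraries but 1 cell in each pool, so it did not work in the pools. There, barcodes positive for more than 1 hashtag were removed instead (1034 in the EV-deficient and 673 in the EV-proficient pool), which leaves doublets within a tumour in place. After these steps 30738 cells of 36706 barcodes remained. Hashtags were assigned by a mixture of 2 Gaussians on log counts per pool and hashtag. Exactly 1 hashtag was found on 52.5% of the EV-deficient and 49.0% of the EV-proficient pool cells past the cell filters (51.3% and 47.6% of all barcodes). The design, fixed beforehand, made the 12 tumours the replicates unless a share under 50% was found in either pool. As the EV-proficient pool fell short, each pool entered the tests as 1 replicate beside the 3 separate libraries, with the batch (separate library or pool) as a covariate. Once cells with more than 1 hashtag were removed the shares were 56.8% and 51.7%, so this choice rests on counting them, and the 12-tumour values stand with the alternatives. The labels do not say which hashtag marks which tumour.

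Cells were clustered with scanpy 1.11.5 in Python 3.11.15 (2000 genes variable within libraries, 30 principal components, 15 neighbours, Leiden resolution 1.0 with leidenalg 0.10.2, seed 0, no integration), which gave 43 clusters. Each was named from 29 marker sets fixed beforehand. A marker counted as detected at a share of at least 0.25 of the cluster's cells and a log2 difference of at least 0.5, and a name needed at least 3 such markers. This naming rule, unlike the markers, was set after the data were seen. Of the 43 clusters, 4 stayed unnamed. The names are broad and were rebuilt from these data, so they may differ from the study's own. All classes named here are "like" classes in that sense.

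Counts were summed per library and class, since cells are not replicates. A library entered with at least 10 cells of a class, and a class was tested with at least 3 libraries per group. Sums were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (TMM scaling, the filterByExpr filter, robust dispersion) with batch and group as terms and Benjamini-Hochberg adjustment at 0.05 within each class. A positive log2 fold change means higher in EV-deficient sites. Levels are given as CPM of the summed counts, as mean ± SD over the 3 separate libraries with the pool's value beside it where useful. The number of replicates n is libraries throughout. Shares of the 10 classes with a mean of at least 0.5% of kept cells were compared by a two-sided exact permutation test of the group labels within batch (40 arrangements, smallest p 0.05) on the difference in percentage points.

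Of 23 gene lists fixed beforehand, 22 were tested: type I interferon response, interferon gamma response, MHC class I and class II antigen presentation, NF-kB inflammatory response, chemokines, senescence-associated secretory phenotype, p53 and senescence growth arrest, proliferation, extracellular vesicle biogenesis and release, efferocytosis and lipid handling, classical and alternative macrophage activation, neutrophil granule and maturation, dendritic cell maturation, cytotoxic lymphocyte, hypoxia and glycolysis, extracellular matrix and myofibroblast, endothelial activation, keratinocyte differentiation, immediate-early and heat-shock (dissociation) genes, and mitochondrially encoded genes. A sex-linked check list had too few measured members (under 5) to be tested. Lists were tested with camera of limma 3.58.1 on voom log-CPM with a preset inter-gene correlation of 0.01, adjusted over the 153 pairs of list and class with at least 5 measured members, and again with an estimated correlation. Member counts are given both over all genes tested and adjusted over the list alone.

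Genes were named by a rule fixed before the data were examined, as were the groups, tests, markers and gene lists called fixed beforehand here. Over all cells summed these were the 10 largest rises and 10 largest falls among genes past the threshold with a mean log2 CPM of at least 4 and the same direction in both batches, and in each class the 5 largest of each. Genes without a common symbol (Gm and Rik models), mitochondrial, ribosomal and sex-linked genes were counted but not named this way. Up to 4 members per discussed list with the smallest adjusted p were added, and vesicle-release genes in epithelial cells whatever their p. Where no gene passed, the 3 with the smallest unadjusted p were given as values. This named 208 genes in 308 pairs of gene and class, of which 102 were past the threshold. Fibroblast markers outside the matrix list, the h_dLNGFR feature and the carcinoma-cell values were chosen after their values were seen.

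Total counts per library ranged from 9737848 to 19039970 UMIs in the separate libraries and were 116523336 and 137590018 in the pools. In simulated counts with 200 changed genes, a 2-fold change was recovered for 54.6% of changed genes in all cells summed, 91.9% in neutrophils, 81.8% in monocytes/macrophages, 77.6% in dendritic cells, 54.2% in fibroblasts, 69.7% in endothelial cells, 10.3% in pericytes and 13.3% in epithelial cells. The share of false calls was 4.5% to 10.3%. These figures come from sums over 15040, 7311, 11200, 8309, 8453, 9918, 3931 and 7992 genes. The share test called 5.5% of 200 simulations with no added difference and 100% with 20 added points. In the comparison of the 8 libraries no adjusted p under 0.05 was possible, so these rates do not describe calls after adjustment there. Intervals of shares are 95% Wilson intervals, and intervals of summed counts are exact Poisson intervals; both cover counting error only.

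Alternatives were DESeq2 1.42.0 in place of edgeR, RLE size factors, no low-count filter, no batch term, the replicate number as a block, the separate libraries alone, the pools alone with 3 hashtag-marked tumours per group, at least 500 genes or at most 10% mitochondrial counts per cell, doublets kept, Leiden resolution 2.0, a hashtag rule of at least 10 counts and 3 times the next, other denominators of shares, and each library left out in turn. The 12-tumour fit with hashtags, the fit on pool cells with exactly 1 hashtag, shares without unnamed cells, fits without the interferon-led clusters 13 and 21, and most other settings of the list tests were added after the data were seen. T cells/ILC, NK cells and B cells were not tested for genes: T cells/ILC had 10 cells in 3 EV-deficient libraries but in only 1 EV-proficient library.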

Results

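To examine what the vesicles of senescent cells do to the tissue around them and to immune recruitment, single-cell transcriptomes were collected from mouse oral sites on day 3 after injection of paclitaxel-treated carcinoma cells that could (EV-proficient) or could not (EV-deficient) release extracellular vesicles. Each group comprised 4 libraries: 3 separate tumours and 1 pool of 3 hashtag-marked tumours. Replicates were separate tumours per the titles. Total UMI counts of the EV-proficient libraries 1, 2 and 3 were 9737848, 11395940 and 19039970, and those of the EV-deficient libraries were 15394373, 17402031 and 16024548. The EV-proficient pool held 116523336 UMIs and the EV-deficient pool 137590018. After filtering, 802, 800 and 1566 cells remained in the separate EV-proficient libraries and 1067, 1333 and 851 in the EV-deficient ones, with 11793 and 12526 cells in the respective pools. The median barcode carried 4763 to 4828 UMIs in the separate EV-proficient libraries and 5003 to 8091 in the EV-deficient ones, against 2780 and 2994 in the pools.

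Neutrophils (9280 cells) and monocytes/macrophages (7436) were the most numerous immune classes, followed by dendritic cells (1298). Epithelial (5502), endothelial (1538), fibroblast (959) and pericyte or smooth muscle cells (147) made up the named non-immune cells that were tested for genes. The separate libraries and the pools drew on different clusters of the myeloid classes. Neutrophils of the separate libraries lay mostly in cluster 3 (66.2% of EV-deficient and 75.1% of EV-proficient neutrophils), while cluster 0 was the largest in the pools (45.0% and 68.8%). Monocytes/macrophages of the separate libraries lay mostly in clusters 4 and 7, while cluster 2 was the largest in the pools (46.3% and 69.2%), with cluster 6 holding 36.8% of this class in the EV-deficient pool. Epithelial cells differed most, with clusters 10, 9 and 14 leading in the EV-deficient pool, cluster 12 holding 58.7% in the EV-proficient pool, and clusters 9, 32 and 25 leading in the separate libraries. Fibroblast cluster 30 lay almost wholly in the EV-proficient pool, with 29.4% of its fibroblasts. Unnamed cells made up 26.3% of the EV-proficient pool and 4.07% of the EV-deficient pool, and 0.675% to 2.63% of the separate libraries.

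To compare the cellular make-up of the sites, the share of each class was calculated per library. Neutrophils, the granulocytes that arrive early at injured tissue, made up 16.4% ± 1.22 (SD, n = 3) of cells in the separate EV-deficient libraries and 29.4% ± 5.08 (SD, n = 3) in the EV-proficient ones. In the pools the shares were 27.4% and 37.4%. T cells and innate lymphoid cells were rare, at 1.18% ± 0.522 (SD, n = 3) of the separate EV-deficient and 0.273% ± 0.131 (SD, n = 3) of the EV-proficient libraries, and 0.335% and 0.187% in the pools. Endothelial cells made up 19.97% ± 8.75 (SD, n = 3) against 10.9% ± 1.38 (SD, n = 3), with 2.29% and 1.78% in the pools. Monocytes/macrophages made up 40.7% ± 10.3 (SD, n = 3) against 39.7% ± 1.74 (SD, n = 3), with 28.3% and 11.2% in the pools.

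Over all 8 libraries the neutrophil share was 12.2 percentage points lower in EV-deficient sites (difference -12.2), and the T cell/ILC share was 0.72 points higher. Each gave p = 0.05 in the two-sided exact permutation test within batch, the smallest p that the 40 arrangements allow. After Benjamini-Hochberg adjustment over the 10 classes each had an adjusted p of 0.25. With this smallest p no class could have reached an adjusted p under 0.05, whatever the shares. Within the separate libraries alone the neutrophil difference was -13.0 points (exact permutation p = 0.1, the smallest possible with 3 against 3), and between the pools it was -9.96 points. The other differences were 6.94 points for endothelial cells (exact permutation p = 0.2), 4.98 for monocytes/macrophages (p = 0.45), 4.08 for epithelial cells (p = 0.25), 0.79 for Schwann cells (p = 0.25), 0.77 for pericytes (p = 0.25), 0.51 for erythroid cells (p = 0.5), 0.21 for fibroblasts (p = 0.75) and -0.49 for dendritic cells (p = 0.65). Pool and separate libraries of 1 group differed widely in recovery: epithelial cells made up 29.0% and 13.9% of the pools against 3.80% ± 0.370 and 3.38% ± 0.793 (SD, n = 3 each) of the separate libraries. The neutrophil p rose to 0.1 without any 1 of the separate EV-deficient libraries or without the EV-proficient pool, when the difference lay between -11.8 and -10.2 points. The endothelial difference fell to 3.72 points without EV-deficient 1 and to 3.84 without EV-deficient 2, and those of pericytes and Schwann cells to 0.35 and 0.38 without EV-deficient 1. The T cell/ILC difference was 0.45 points without EV-deficient 1, and its p rose to 0.1 without the EV-proficient pool. Uncalled differences changed sign: monocytes/macrophages to -2.15 without the EV-proficient pool, epithelial cells to -2.21 and dendritic cells to 0.65 without the EV-deficient pool, dendritic cells to 0.56 without EV-proficient 2, erythroid cells to -0.0019 without EV-deficient 3 and fibroblasts to -0.13 without EV-proficient 1. These are differences of plain group means, so leaving out a library also changes the weight of pools against separate libraries in its group. Without 1 pool, only 1 group holds a pool. Such values and their p then mix the difference between batches with that between groups.

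**Figure D1:**
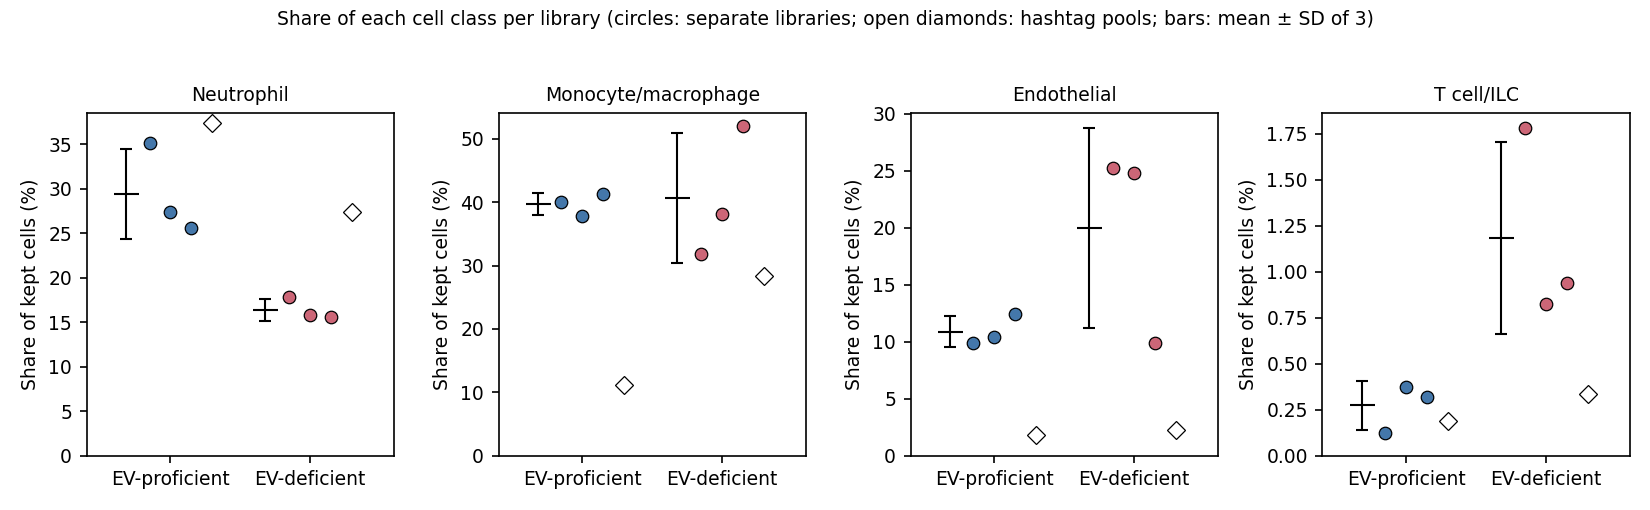
Share of kept cells (percent, vertical axis) that were neutrophils, monocytes/macrophages, endothelial cells and T cells/ILC in each EV-proficient and EV-deficient library, with the mean ± SD of the 3 separate libraries and the pools drawn as diamonds. Neutrophils made up 15.6% to 17.8% of the separate EV-deficient libraries and 25.6% to 35.2% of the EV-proficient ones.

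To find transcripts that differed at the sites as a whole, UMIs of all kept cells were summed per library. The genes past the threshold included interferon-induced ones among the rises and collagen and neutrophil ones among the falls. Isg15, a ubiquitin-like interferon-induced protein, rose by a log2 fold change of 1.16 (SE 0.14, edgeR with Benjamini-Hochberg adjusted p = 0.0334), from 57.1 ± 5.42 to 121 ± 24.5 CPM (SD, n = 3 separate libraries each) and from 71.4 to 198.6 CPM between the pools. Col12a1, a fibril-associated collagen, fell by 1.52 on the log2 scale (SE 0.12, edgeR Benjamini-Hochberg adjusted p = 0.00974), from 115 ± 18.3 to 40.1 ± 3.80 CPM (SD, n = 3). Cxcr2, the chemokine receptor of neutrophils, fell by 1.07 on the log2 scale (SE 0.14, edgeR Benjamini-Hochberg adjusted p = 0.0334), from 131 ± 17.6 to 56.7 ± 4.2 CPM (SD, n = 3). In edgeR 39 of 15194 genes passed, 18 higher and 21 lower, and all 39 had the same direction in both batches.

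The largest rises in all cells summed were Ifi27l2a (log2 fold change 1.31), Ifi44 (1.25), the interferon regulator Irf7 (1.23), Isg15, the galectin-3 binding protein Lgals3bp (1.09), Bst2 or tetherin (1.08), the class Ib MHC gene H2-T23 (0.98), Plac8 (0.95), Ifitm3 (0.92) and Xaf1 (0.92). The largest falls were Col12a1, the carbonic anhydrase Car4 (-1.47), the Wnt antagonist Sfrp1 (-1.08), Cxcr2, the mesenchymal cadherin Cdh11 (-1.07), tenascin C (Tnc, -1.04), Mirt1 (-1.03), Il1f9 (-0.99), Tarm1 (-0.93) and the G-CSF receptor Csf3r (-0.87). Their edgeR Benjamini-Hochberg adjusted p lay between 0.00974 and 0.0461. Isg15 (ENSMUSG00000035692) lies on chromosome 4 at 156199424 to 156200818, Col12a1 (ENSMUSG00000032332) on chromosome 9 at 79598991 to 79718831 and Cxcr2 (ENSMUSG00000026180) on chromosome 1 at 74153989 to 74161246 of GRCm38, all protein-coding. Leaving out 1 library changed the count of 39 to 0 without EV-deficient 2, the EV-deficient pool or the EV-proficient pool, to 1 without EV-proficient 1 or 2, to 2 without EV-proficient 3 and to 252 without EV-deficient 3. The separate libraries alone gave 0 changed genes in edgeR (2234 had an unadjusted p under 0.05 over all 8 libraries, and DESeq2 called 741), and the fit without the batch term gave 1.

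As groups, 7 of 29 type I interferon genes rose in all cells summed (26 adjusted over the list alone), with a median log2 fold change of 0.70 (camera Benjamini-Hochberg adjusted p = 1.8e-17; 0.331 with an estimated correlation). Of 15 MHC class I presentation genes 4 rose (13 adjusted over the list alone; median 0.55, adjusted p = 1.85e-09; 0.331 with an estimated correlation). They were the immunoproteasome subunit Psmb9 (0.68), the class I transactivator Nlrc5 (0.83), H2-Q4 (0.81) and H2-T23. None of 19 interferon gamma genes passed over all genes in edgeR, 10 adjusted over the list alone (median 0.59, camera adjusted p = 1.35e-06; 0.331 with an estimated correlation). Of 24 extracellular matrix genes 4 fell (16 adjusted over the list alone; median -0.56, adjusted p = 5.27e-14; 0.331 with an estimated correlation). Those past the threshold were Col12a1, Tnc, Col5a1 (-0.84) and Col5a2 (-0.74). Of 22 neutrophil granule and maturation genes 2 fell, Cxcr2 and Csf3r (13 adjusted over the list alone; median -0.62, adjusted p = 4.39e-08; 0.364 with an estimated correlation). These 2 are neutrophil markers, and the neutrophil share was lower by the values given above. None of 19 efferocytosis and lipid-handling genes passed over all genes, 5 adjusted over the list alone (median 0.44, camera adjusted p = 0.00241; 0.538 with an estimated correlation).

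Immediate-early and heat-shock genes, which dissociation can induce, had a median log2 fold change of 0.20 in all cells summed (0 of 24 passed, 2 adjusted over the list alone; camera Benjamini-Hochberg adjusted p = 0.0351; 0.551 with an estimated correlation). Mitochondrially encoded genes had a median of -0.20 (0 of 13 passed, 1 adjusted over the list alone; adjusted p = 0.0329; 0.538 with an estimated correlation). In all cells the efferocytosis call ended without EV-deficient 3 (median 0.15), the immediate-early call without EV-deficient 3 or EV-proficient 2 or 3 (0.16 to 0.18), and the mitochondrial call without EV-deficient 3, EV-proficient 1 or either pool (-0.16 to -0.046). Immediate-early genes were at 0.13 without the EV-proficient pool.

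To ask whether neutrophils themselves differed, their counts were summed per library. The genes that rose in this class included interferon-induced ones. Ifitm6, a member of the interferon-induced transmembrane family, rose by a log2 fold change of 1.36 (SE 0.13, edgeR Benjamini-Hochberg adjusted p = 1.03e-06), from 46.7 ± 9.46 to 105 ± 9.58 CPM (SD, n = 3) and from 36.1 to 115.6 CPM between the pools. Isg15 rose by 1.39 (SE 0.20, edgeR Benjamini-Hochberg adjusted p = 0.0155), from 133 ± 3.02 to 329.6 ± 124 CPM (SD, n = 3). Ifitm3 (1.07), Rtp4 (1.02), Xaf1 (1.09), Ifi204 (0.98), Oasl1 (0.88) and the interferon-gamma-induced GTPase Ifi47 (0.97) rose, as did the stress regulator Nupr1 (1.09). The rises in H2-T23 and Psmb8 were 0.67 and 0.51. In edgeR 140 of 7466 genes changed, 99 higher and 41 lower. Ifitm6 (ENSMUSG00000059108) lies on chromosome 7 at 141015699 to 141017924.

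The largest falls in neutrophils were Pde6a (-2.65), Trim2 (-2.10) and Slx1b (-1.71), with edgeR Benjamini-Hochberg adjusted p of 0.000153, 0.0155 and 0.0429. These were carried by the EV-proficient pool, in which Pde6a stood at 111.9 CPM against 13 in the EV-deficient pool, 14.7 ± 0.473 in the separate EV-proficient and 6.07 ± 3.16 in the separate EV-deficient libraries (SD, n = 3 each). The same 3 genes led the unnamed cluster 1, which held 2958 of its 2974 cells in that pool at a median of 857 UMIs. Col1a2 (-1.32, adjusted p = 0.0315) and Col3a1 (-0.93, adjusted p = 0.0436), fibroblast collagens, fell too, at 7.1 ± 0.608 against 16.2 ± 11.5 CPM of Col1a2 (SD, n = 3) and 46.9 against 114.6 CPM in the pools.

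Of 25 type I interferon genes 8 rose in neutrophils (12 adjusted over the list alone; median 0.78, camera Benjamini-Hochberg adjusted p = 1.41e-18; 0.331 with an estimated correlation). Of 14 MHC class I genes 2 rose (5 adjusted over the list alone; median 0.27, adjusted p = 3.24e-05; 0.331 with an estimated correlation). Of 10 interferon gamma genes 1 rose (5 adjusted over the list alone; median 0.38, adjusted p = 0.000869; 0.389 with an estimated correlation). Of 7 measured matrix genes 2 fell (4 adjusted over the list alone; median -0.93, adjusted p = 0.00314; 0.389 with an estimated correlation). The NF-kB list was higher (median 0.14, 0 of 21 over all genes and adjusted over the list alone, adjusted p = 0.0262; 0.331 with an estimated correlation). Chemokines were higher too (median 0.20, 0 of 12 by both counts, adjusted p = 0.0243; 0.389 with an estimated correlation). Markers of other cell types were lower, namely alternative macrophage genes (median -0.33, 0 of 11, 2 adjusted over the list alone, adjusted p = 0.0304; 0.331 with an estimated correlation). So were keratinocyte genes (median -0.35, 0 of 5, 1 adjusted over the list alone, adjusted p = 0.03; 0.331 with an estimated correlation). Immediate-early genes were lower here (median -0.11, 0 of 24 by both counts, adjusted p = 0.0285; 0.538 with an estimated correlation), although their median was 0.14 in the pools alone. Mitochondrial genes were higher (median 0.50, 0 of 11 by both counts, adjusted p = 0.0103; 0.642 with an estimated correlation). Granule and maturation genes showed no call within neutrophils (median 0.04, adjusted p = 0.12; 1 of 21 higher, Hdc, also adjusted over the list alone). Without either pool the calls of interferon gamma (0.34 and 0.30), matrix (-0.62 and -0.60) and chemokine genes (0.22 and 0.24) ended, and class I genes were at 0.16 and 0.17. Calls also ended for chemokines without EV-deficient 1 (0.28), alternative macrophage genes without EV-deficient 3 (-0.35), NF-kB genes without EV-proficient 2 (0.16), keratinocyte genes without any separate library but EV-deficient 2 (-0.32 to -0.20), immediate-early genes without EV-deficient 2 or EV-proficient 1 or 3 (-0.11 to -0.053) and mitochondrial genes without EV-deficient 1 or 2 or EV-proficient 2 (0.31 to 0.35). Chemokines were at 0.31 and 0.33 without EV-deficient 3 or EV-proficient 3, and immediate-early genes at -0.18 without the EV-deficient pool. The 140 changed genes became 61 without EV-deficient 2, 22 without the EV-deficient pool, 73 without EV-proficient 3, 23 without the EV-proficient pool, 20 in the separate libraries alone and 7 without the batch term. Ifitm3, Ifitm6 and Rtp4 stayed past the threshold whichever library was left out.

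Monocytes/macrophages showed the most changed genes of any class, 338 of 11412 (246 higher and 92 lower in edgeR). The rises included 8 of 29 type I interferon genes and 4 of 19 efferocytosis and lipid-handling genes, lists that were not called with an estimated correlation (camera adjusted p = 0.331 and 0.389). In the separate libraries cluster 4 held 55.8% of EV-deficient and 45.9% of EV-proficient cells of this class, cluster 7, of low UMI counts, held 30.4% and 43.6%, and the interferon-led cluster 21 held 9.06% and at most 4.64%. Ifi27l2a rose by a log2 fold change of 1.30 (SE 0.12, edgeR Benjamini-Hochberg adjusted p = 7.69e-05), from 320.0 ± 41.2 to 770.1 ± 129 CPM (SD, n = 3). Apoe, the lipid carrier, rose by 0.98 (SE 0.14, adjusted p = 0.00259), from 6913 ± 1390 to 12733 ± 1303 CPM (SD, n = 3), and Trem2, a lipid-sensing receptor, by 0.58 (SE 0.09, adjusted p = 0.00305), from 258 ± 14.5 to 383 ± 28.6 CPM (SD, n = 3). Gpnmb, a glycoprotein of phagocytic macrophages, rose by 1.6 (SE 0.26, adjusted p = 0.03), from 145 ± 52.1 to 395 ± 80.7 CPM (SD, n = 3). Apoe and Gpnmb were among the markers that named this class. Apoe (ENSMUSG00000002985) lies on chromosome 7 at 19696109 to 19699188, Trem2 (ENSMUSG00000023992) on chromosome 17 at 48346401 to 48354147 and Gpnmb (ENSMUSG00000029816) on chromosome 6 at 49036546 to 49070929.

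Further large rises in monocytes/macrophages were Ifi44 (1.59), the surface receptor Slamf7 (1.48), Irf7 (1.41) and the leukotriene C4 synthase Ltc4s (1.29), and the lysosomal protease Ctsd rose by 0.48. The largest falls were Tanc2 (-0.93), Hebp1 (-0.90), the integrin Itga1 (-0.76), the metallothionein Mt2 (-0.76) and the growth factor Hbegf (-0.70). Their edgeR Benjamini-Hochberg adjusted p lay between 0.00545 and 0.0471. Of 29 type I interferon genes 8 rose (19 adjusted over the list alone; median 0.65, camera adjusted p = 4.61e-18; 0.331 with an estimated correlation). Of 15 MHC class I genes 7 rose (13 adjusted over the list alone; median 0.49, adjusted p = 2.71e-09; 0.331 with an estimated correlation). Among them were H2-T23 at 1.14, H2-Q7 at 0.67, Psmb9 at 0.57 and Psmb8 at 0.49. Of 19 efferocytosis and lipid-handling genes 4 rose by both counts (median 0.26, adjusted p = 0.001; 0.389 with an estimated correlation). These were Apoe, Trem2, Gpnmb and Ctsd. No interferon gamma gene of 16 passed over all genes, 3 adjusted over the list alone (median 0.33, camera adjusted p = 0.00058; 0.372 with an estimated correlation). Of 24 NF-kB genes 1 rose, Cd83 at 0.71 (3 adjusted over the list alone; median 0.27, adjusted p = 3.88e-05; 0.389 with an estimated correlation).

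Proliferation genes were lower in monocytes/macrophages as a list (median -0.30, 0 of 27 by both counts, camera Benjamini-Hochberg adjusted p = 0.000352; 0.6 with an estimated correlation), but at Leiden resolution 2.0 their median was 0.033. Matrix genes were lower too (median -0.66, 0 of 14 over all genes, 1 adjusted over the list alone, adjusted p = 3.24e-05; 0.331 with an estimated correlation). Immediate-early genes were higher as a list, with Socs3 at 0.57 and Atf3 at 0.45 past the threshold (2 of 24, 5 adjusted over the list alone; median 0.18, adjusted p = 0.00288; 0.551 with an estimated correlation). Mitochondrial genes were lower, 1 of 13 by both counts, mt-Nd3 at -1.21 (median -0.17, adjusted p = 0.00183; 0.431 with an estimated correlation). Without EV-deficient 3 the mitochondrial call ended (-0.075) and NF-kB and proliferation genes were at 0.16 and -0.20. Without EV-deficient 2 efferocytosis and proliferation genes were at 0.39 and -0.48, and without EV-proficient 2 mitochondrial and proliferation genes were at -0.26 and -0.13. The 338 changed genes became 46 without the EV-deficient pool, 48 without the EV-proficient pool, 161 without EV-proficient 2, 48 in the separate libraries alone and 0 without the batch term. Apoe, H2-T23, Ifi27l2a, Mt2, Slamf7 and Trem2 stayed past the threshold whichever library was left out.

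**Figure D2:**
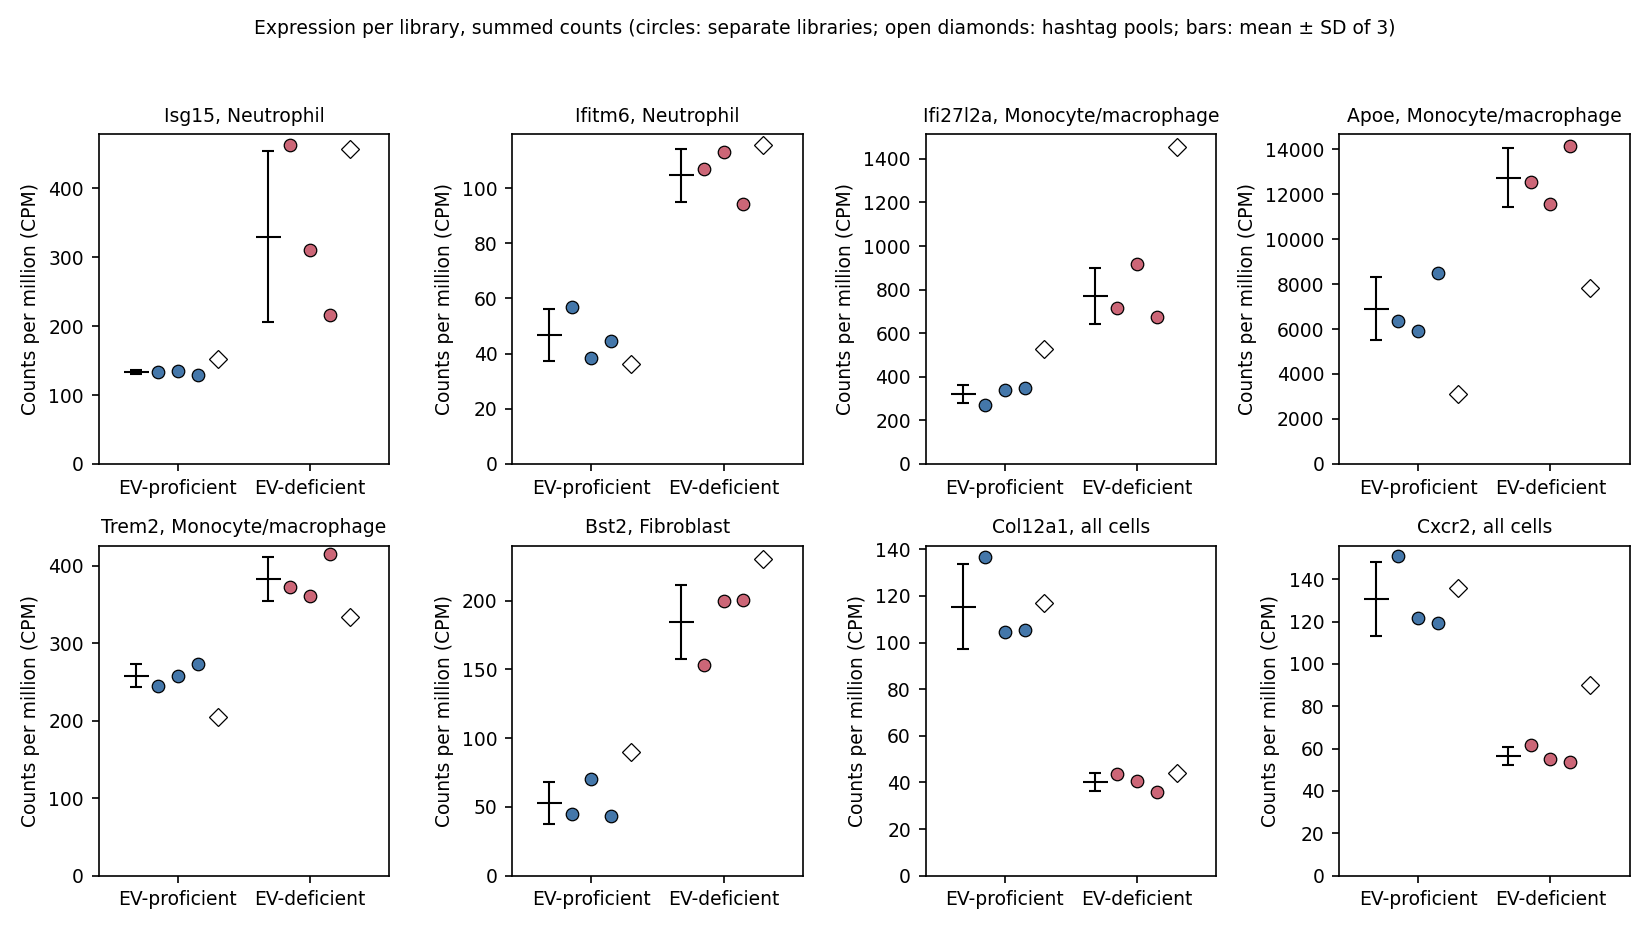
CPM (vertical axis) in each EV-proficient and EV-deficient library of Isg15 and Ifitm6 in neutrophils, Ifi27l2a, Apoe and Trem2 in monocytes/macrophages, Bst2 in fibroblasts, and Col12a1 and Cxcr2 in all cells summed, with the mean ± SD of the 3 separate libraries and the pools as diamonds. Trem2 averaged 383 CPM in the separate EV-deficient and 258 CPM in the EV-proficient libraries, and Col12a1 averaged 40.1 and 115 CPM.

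Dendritic cells, all of cluster 8, were led by class II genes and Ccl17, but 9 monocyte/macrophage markers, Chil3 and Arg1 among them, were detected beside 7 dendritic ones. At Leiden resolution 2.0 only 651 cells were named dendritic, and a cluster of 480 cells led by Mmp12 and Chil3 was named monocyte/macrophage. In edgeR 29 of 8497 genes changed, 18 higher and 11 lower. Tmem176b, a membrane protein of dendritic cells and macrophages, rose by a log2 fold change of 1.07 (SE 0.15, Benjamini-Hochberg adjusted p = 0.00243), from 61.5 ± 14.4 to 123 ± 25.7 CPM (SD, n = 3). Ifi27l2a (1.17), the guanylate-binding protein Gbp2 (1.08), the lipid transfer protein Pltp (1.00) and Rtp4 (0.89) rose. The platelet and dendritic lectin receptor Clec1b (-1.27), Zc3h12c (-1.04), Ppfibp1 (-1.01), Pecam1 (-0.89) and Pla1a (-0.87) fell. Their edgeR Benjamini-Hochberg adjusted p lay between 0.0113 and 0.0454. MHC class II genes, which present antigen to helper T cells, were higher as a list (median 0.27, 0 of 14 over all genes, 2 adjusted over the list alone, camera adjusted p = 0.000141; 0.331 with an estimated correlation), with H2-DMa at 0.48 (adjusted p = 0.0545).

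Of 24 type I interferon genes 2 rose in dendritic cells, Ifi27l2a and Rtp4 (10 adjusted over the list alone; median 0.61, camera Benjamini-Hochberg adjusted p = 3.93e-14; 0.331 with an estimated correlation). The MHC class I list was higher (median 0.38, 0 of 15 over all genes, 8 adjusted over the list alone, adjusted p = 1.45e-08; 0.331 with an estimated correlation). The interferon gamma list was higher as well (median 0.24, Gbp2 of 10 over all genes, 4 adjusted over the list alone, adjusted p = 0.00115; 0.331 with an estimated correlation). Efferocytosis genes were higher as a list (median 0.23, 0 of 18 over all genes, 5 higher and 1 lower adjusted over the list alone, adjusted p = 0.00154; 0.331 with an estimated correlation). Immediate-early genes were also higher (median 0.16, 0 of 24 by both counts, adjusted p = 0.00125; 0.389 with an estimated correlation). Without the EV-deficient or the EV-proficient pool medians fell to 0.097 and 0.096 for class II (the call ended without the latter), 0.26 and 0.25 for class I, 0.15 and 0.14 for efferocytosis and 0.081 and 0.078 for immediate-early genes. Interferon gamma genes were at 0.44 to 0.47 without EV-deficient 3 or EV-proficient 2 or 3. The count of 29 became 59 without EV-deficient 1, 14 without EV-deficient 2, 15 without the EV-deficient pool, 18 without EV-proficient 2, 14 without the EV-proficient pool, 12 in the separate libraries alone, 1 at Leiden resolution 2.0 and 0 without the batch term. Tmem176b alone of the 10 named genes stayed past the threshold whichever library was left out.

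In fibroblasts 3 of 8674 genes changed in edgeR, all higher. Bst2, the interferon-induced tetherin that holds virions and vesicles at the cell surface, rose by a log2 fold change of 1.68 (SE 0.19, Benjamini-Hochberg adjusted p = 0.00406), from 52.7 ± 15.1 to 184 ± 27 CPM (SD, n = 3) and from 90.1 to 230.2 CPM between the pools. Lgals3bp rose by 1.46 (adjusted p = 0.0222), from 36.5 ± 11.6 to 118 ± 23.4 CPM (SD, n = 3), and the class I heavy chain H2-D1 by 1.33 (adjusted p = 0.0222), from 73.1 ± 19.3 to 213 ± 21.5 CPM (SD, n = 3). Bst2 (ENSMUSG00000046718) lies on chromosome 8 at 71534255 to 71537456. Type I interferon genes had their highest median in this class, 1.45, with 1 of 20 past the threshold (12 adjusted over the list alone; camera adjusted p = 2.57e-19; 0.331 with an estimated correlation). Class I presentation genes were higher (median 0.94, 1 of 12 over all genes, 9 higher and 1 lower adjusted over the list alone, adjusted p = 7.83e-08; 0.331 with an estimated correlation). Interferon gamma genes were higher (median 1.27, 0 of 9 over all genes, 7 adjusted over the list alone, adjusted p = 1.96e-07; 0.331 with an estimated correlation).

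Matrix genes, the main product of fibroblasts, were not called within them (median -0.11, 0 of 24 over all genes, 4 lower adjusted over the list alone, camera Benjamini-Hochberg adjusted p = 0.106). Immediate-early genes were higher in fibroblasts (median 0.20, 0 of 24 over all genes, 10 adjusted over the list alone, adjusted p = 2.66e-05; 0.364 with an estimated correlation). Efferocytosis genes were also higher (median 0.37, 0 of 12 by both counts, adjusted p = 0.00282; 0.431 with an estimated correlation). Mitochondrial genes were lower (median -0.30, 0 of 12 by both counts, adjusted p = 0.00154; 0.389 with an estimated correlation). Hypoxia genes were lower too (median -0.21, 0 of 21 by both counts, adjusted p = 0.0458; 0.743 with an estimated correlation). In fibroblasts the efferocytosis call ended without EV-proficient 2 (0.16), the mitochondrial one without the EV-proficient pool (-0.18; -0.17 without the other pool) and the hypoxia one without EV-deficient 1 or 2 or EV-proficient 1 or 2 (-0.15 to -0.066; -0.47 to -0.35 without EV-deficient 3 or either pool). Immediate-early genes were at 0.0061 without EV-deficient 3, 0.088 without EV-proficient 2 and 0.35 without EV-proficient 1. The 3 changed genes became 1 without EV-deficient 1 or 2, 20 without EV-deficient 3 and 8 without EV-proficient 3, and only Bst2 stayed past the threshold whichever library was left out.

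In endothelial cells 13 of 10110 genes changed in edgeR, 10 higher and 3 lower. The clusters they came from differed as well: in the separate libraries cluster 11 held 77.1% of EV-deficient and 53.8% of EV-proficient endothelial cells, and cluster 17 held 21.5% and 43.7%. The inhibitor of differentiation Id1 rose by a log2 fold change of 0.96 (SE 0.15, Benjamini-Hochberg adjusted p = 0.0301), from 403 ± 110 to 805 ± 27.6 CPM (SD, n = 3), and Icam1, the leukocyte adhesion molecule, by 0.77 (SE 0.13, adjusted p = 0.0301), from 177 ± 6.09 to 311 ± 26.6 CPM (SD, n = 3). The flow-responsive factor Klf2 (1.19), the stress factor Atf3 (1.07), Rnd1 (1.01), Tppp (0.91) and H2-T23 (0.81) rose. The cell-cycle genes Tcf19 (-1.19), Hist1h3c (-1.10) and Diaph3 (-1.03) fell, with edgeR Benjamini-Hochberg adjusted p between 0.0402 and 0.0445. Proliferation genes were lower as a list (median -0.51, 0 of 28 over all genes, 11 adjusted over the list alone, camera adjusted p = 3.08e-15; 0.331 with an estimated correlation). Mki67 was at -0.88 (adjusted p = 0.0772), Rrm2 at -0.89 and Mcm6 at -0.63 (adjusted p = 0.0977 each). In the EV-deficient and EV-proficient pools Mki67 stood at 94.5 and 209.2 CPM and Klf2 at 1066 and 476.5 CPM.

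Of the interferon lists in endothelial cells, type I genes had a median of 0.30 (0 of 24 over all genes, 3 adjusted over the list alone, camera Benjamini-Hochberg adjusted p = 7e-07; 0.389 with an estimated correlation). MHC class I genes had a median of 0.50 (1 of 15, H2-T23, 9 adjusted over the list alone, adjusted p = 1.08e-09; 0.331 with an estimated correlation). Interferon gamma genes had a median of 0.48 (0 of 16, 4 adjusted over the list alone, adjusted p = 2.71e-07; 0.389 with an estimated correlation). Endothelial activation genes were higher (median 0.09, 1 of 18 by both counts, Icam1, adjusted p = 0.0394; 0.389 with an estimated correlation), although their median was -0.21 in the pools alone. So were chemokines (median 0.23, 0 of 16 by both counts, adjusted p = 0.00504; 0.331 with an estimated correlation). Efferocytosis genes were also higher (median 0.21, 0 of 15 by both counts, adjusted p = 0.0349; 0.435 with an estimated correlation). Immediate-early genes were higher as a list, with 2 of 24 past the threshold, Klf2 and Atf3 (9 adjusted over the list alone; median 0.41, adjusted p = 3e-11; 0.331 with an estimated correlation). Type I medians were 0.12 without EV-deficient 2, 0.11 without EV-proficient 3, 0.20 and 0.19 without either pool and 0.54 without EV-proficient 1. Without the EV-deficient or EV-proficient pool the calls of chemokines (-0.083 and 0.054) and efferocytosis genes (0.015 and 0.0072) ended, and that of endothelial activation ended without EV-deficient 3 or EV-proficient 1 or 2 (0.080 to 0.16). Without EV-proficient 3 chemokines, endothelial activation and interferon gamma genes were at 0.36, 0.19 and 0.30, and without EV-proficient 1 efferocytosis and immediate-early genes at 0.33 and 0.63. The count of 13 became 0 without EV-deficient 1, 2 or 3 or without EV-proficient 2 or 3, 6 without either pool, 228 without EV-proficient 1, 5 in the separate libraries alone and 0 without the batch term. No named endothelial gene kept its call whichever library was left out. Among all endothelial genes 1009 had an unadjusted p under 0.05, and DESeq2 called 52.

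Pericytes or smooth muscle cells could be tested with 3 libraries per group, 2 separate and the pool. In edgeR 21 of 4241 genes changed, 10 higher and 11 lower, in sums of 12 to 33 cells. Collagen VI and V genes were among the falls. At Leiden resolution 2.0 the count was 15, 1 higher and 14 lower, of which 6 were among the 21. There a cluster of 71 cells led by Mgp, Fabp4 and Ptprb, leading genes of cluster 26 too, was named endothelial, and clusters of 50 and 137 cells were named pericytes, the larger with 106 cells in the EV-deficient pool. Col6a3 fell by 2.61 on the log2 scale (SE 0.30, Benjamini-Hochberg adjusted p = 0.00221), from 428 ± 11 to 68.2 ± 39.2 CPM (SD, n = 2 separate libraries each). Col6a1 (-3.14), the procollagen protease Bmp1 (-3.10), Col5a1 (-2.59), C1qtnf6 (-2.38) and Col5a2 (-2.35) fell. Id1 rose by 1.95 (SE 0.23, edgeR Benjamini-Hochberg adjusted p = 0.00221). Isg15 (2.15), Ifi27l2a (2.00), Ier5l (1.67), endothelin (Edn1, 1.6), Bst2 (1.49), Klf4 (1.28) and Atf3 (1.22) rose, with edgeR Benjamini-Hochberg adjusted p up to 0.0298. This cluster, 26, also carried endothelial genes. Matrix genes were lower, 6 of 19 (13 adjusted over the list alone; median -2.35, camera adjusted p = 4.07e-13; 0.331 with an estimated correlation).

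Type I interferon genes were higher as a list in pericytes, with 3 of 15 past the threshold (9 adjusted over the list alone; median 1.33, camera Benjamini-Hochberg adjusted p = 6.97e-09; 0.364 with an estimated correlation). Class I presentation genes were higher as a list (median 1.02, 0 of 12 over all genes, 10 higher and 1 lower adjusted over the list alone, adjusted p = 1.29e-08; 0.331 with an estimated correlation). The interferon gamma list was also higher (median 1.13, 0 of 8 over all genes, 4 adjusted over the list alone, adjusted p = 6.72e-06; 0.389 with an estimated correlation). Immediate-early genes were higher too, with 1 of 23 past the threshold, Atf3 (13 higher and 1 lower adjusted over the list alone; median 0.72, adjusted p = 5.77e-10; 0.389 with an estimated correlation). Endothelial activation genes were higher (median 0.40, 0 of 10 by both counts, adjusted p = 0.00886; 0.347 with an estimated correlation). Alternative macrophage genes were higher (median 0.37, 1 of 5 by both counts, Klf4, which smooth muscle also expresses, adjusted p = 0.0329; 0.389 with an estimated correlation). Type I genes were at 0.85 without the EV-deficient pool. The alternative macrophage call ended without EV-deficient 2 or either pool (0.13 to 0.24; 0.87 without EV-deficient 1 and 0.77 without EV-proficient 1), and the endothelial activation call without EV-deficient 1 (0.44; 0.26 and 0.22 without EV-proficient 1 or 3). The count of 21 became 13 without EV-deficient 1, 11 without EV-deficient 2, 40 without the EV-deficient pool, 42 without EV-proficient 1 and 53 without the EV-proficient pool. Bmp1, Col5a2, Col6a3 and Id1 stayed past the threshold whichever library was left out.

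**Figure D3:**
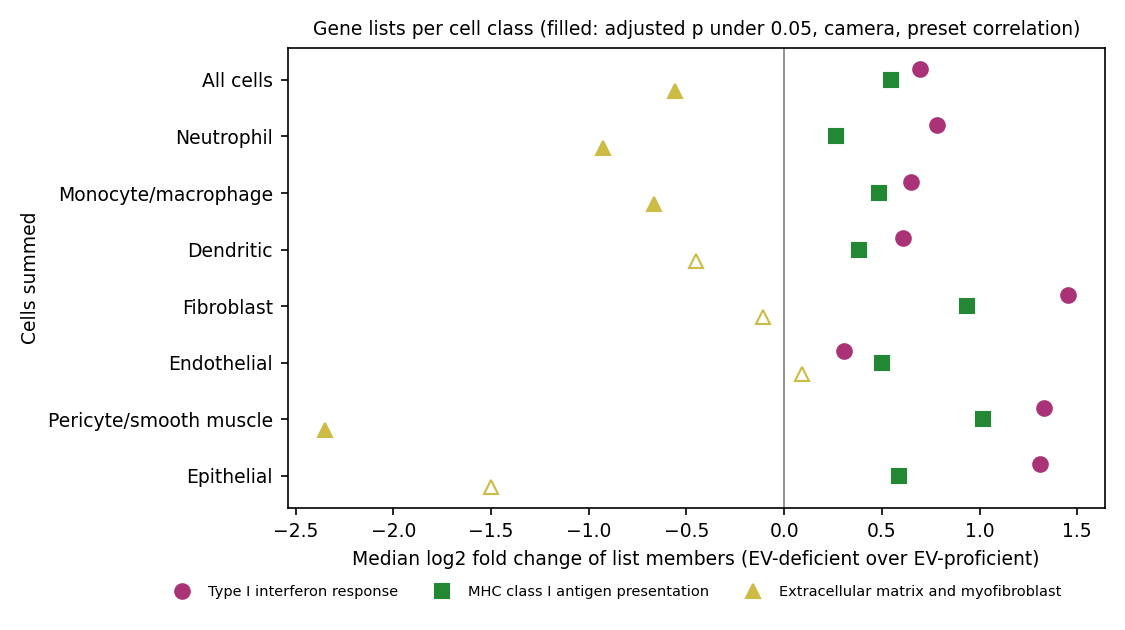
Median log2 fold change (EV-deficient over EV-proficient, horizontal axis) of the type I interferon, MHC class I and extracellular matrix lists in all cells summed and in each class (vertical axis), with filled points where the camera adjusted p was under 0.05. The type I interferon medians ran from 0.30 in endothelial cells to 1.45 in fibroblasts, and the matrix median was lowest in pericytes at -2.35.

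Epithelial cells, which include normal keratinocytes and carcinoma cells, held 5502 cells, of which 3629 lay in the EV-deficient pool. In edgeR 0 of 8271 genes passed; 552 had an unadjusted p under 0.05, DESeq2 called 7 genes and edgeR without the low-count filter 25. The smallest unadjusted p belonged to Tmem176a (log2 fold change 2.25), Clca3b (2.05) and Tmem176b (1.84), each with a Benjamini-Hochberg adjusted p of 0.705. Type I interferon genes had a median of 1.31 (0 of 15 by both counts, camera adjusted p = 8.43e-06; 0.389 with an estimated correlation). MHC class I genes had a median of 0.59 (0 of 14, 1 adjusted over the list alone, adjusted p = 3.88e-05; 0.389 with an estimated correlation), and chemokines one of 0.49 (0 of 9 by both counts, adjusted p = 0.0112; 0.389 with an estimated correlation). Mitochondrial genes were lower (median -0.59, 0 of 12, 2 adjusted over the list alone, adjusted p = 5.62e-08; 0.331 with an estimated correlation). Without either pool the calls of class I genes (0.39 each) and chemokines (0.16 and 0.39) ended. Class I genes were at 0.95 without EV-deficient 1 and 1.03 without EV-proficient 3, and chemokines at 0.087 without EV-deficient 2 and 0.23, 0.17 and 1.37 without EV-proficient 1, 2 and 3. Matrix genes had a median of -1.50 with no call (0 of 7, 1 lower adjusted over the list alone, adjusted p = 0.0868).

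Since release was blocked genetically by a gene that the labels do not name, the 25 measured genes of vesicle biogenesis and release were read in epithelial cells. Their log2 fold changes ran from -0.59 (Exph5) to 0.87 (Cd81), with edgeR Benjamini-Hochberg adjusted p of 0.705 or more. Rab27b, a GTPase of vesicle docking, was at 0.22 (SE 0.30, adjusted p = 0.857), with 65.0 ± 16.1 CPM in EV-deficient and 53.5 ± 26.1 CPM in EV-proficient separate libraries (SD, n = 3 each). The block was in the injected cells, of which the separate libraries may hold few. Clusters rich in h_dLNGFR, assumed below to be carcinoma cells, held 1 to 5 cells per separate library, beside 19 to 59 other epithelial cells. If so, these CPM values read mostly cells that were not altered. Rab27a had too few counts in epithelial cells to be tested; in all cells summed it was at -0.52 (adjusted p = 0.105), the 1 of 28 vesicle genes that passed there, as lower, adjusted over the list alone. As a list, vesicle genes were not called in any class, with camera adjusted p from 0.279 in endothelial cells to 0.879 in pericytes. A 3' count reads transcript level and would not show a coding change that leaves the transcript in place.

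Lists without a call in any class, by camera with Benjamini-Hochberg adjustment, were the senescence-associated secretory phenotype (adjusted p 0.114 to 0.848), p53 and senescence growth arrest (0.0982 to 0.879), classical macrophage activation (0.0961 to 0.765), cytotoxic lymphocyte genes (0.174 to 0.848) and dendritic cell maturation (0.106 to 0.759). Of the 153 pairs of list and class 59 were called with the preset correlation and 0 with the estimated one, for which the adjusted p of these 59 lay between 0.331 and 0.743. Genes of near-identical families, such as the class I H2 genes, the Ifitm, Ifi204 and Gbp families and Tgtp1 with Tgtp2, can share reads, and their single values are uncertain.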

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

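The tests of free RNA from interferon-responding cells and of free fibroblast RNA read in neutrophils were chosen before their results were seen; the splits of the libraries and the tests of clusters 13 and 21, of the pool lanes, of the neutrophil share and of fibroblast numbers were chosen after. Of 198 groups of 4 libraries examined with Dixon's test, 22 had 1 library far from the other 3, where chance alone gives about 1 in 20 groups, or 5%. In 19 of the 22 that library was the pool. Among shares of cells, epithelial cells stood apart in both pools, at 29.0% in the EV-deficient and 13.9% in the EV-proficient pool, and unnamed cells too, at 4.07% and 26.3%. The monocyte/macrophage share was lowest in the EV-proficient pool, at 11.2%.

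In all cells summed the EV-proficient pool stood apart in Ifitm3 (356.8 CPM), Tnc (220.8 CPM) and H2-Q4 (11.8 CPM), the EV-deficient pool in Il1f9 (36.0 CPM), and both pools were lowest in Nlrc5 (5.7 CPM in the EV-deficient and 3.2 CPM in the EV-proficient pool). EV-proficient 1 was highest of its group in Tarm1 (188.9 CPM). In neutrophils the EV-proficient pool was highest in Nupr1 (20.5 CPM), Pde6a (111.9 CPM) and Trim2 (95.7 CPM), the EV-deficient pool was highest in Col1a2 (46.9 CPM), and EV-deficient 3 was lowest in Xaf1 (17.5 CPM). In monocytes/macrophages Mt2 was highest in the EV-proficient pool (879.7 CPM), Hbegf in EV-proficient 2 (217.7 CPM), and Ctsd was lowest in the EV-deficient pool (2099.1 CPM). In endothelial cells Id1 was lowest in the EV-deficient pool (533.3 CPM) and Icam1 in the EV-proficient pool (93.3 CPM).

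The group difference itself differed between separate libraries and pools, by edgeR's test of the interaction with Benjamini-Hochberg adjustment, for 3 genes in neutrophils (Edn1, Gm37144 and Gm10062), 5 in dendritic cells (mt-Atp8, mt-Rnr1, Samsn1, Car2 and Traf1), 3 in endothelial cells (Il1b, Mmp9 and S100a8) and 3 in pericytes (Il1b, Crispld2 and Adamts4). None of these was among the genes called between the groups in the same class. Il1b in endothelial cells, for example, differed by -2.27 on the log2 scale in the separate libraries and by 0.72 in the pools (interaction adjusted p = 0.0042). Il1b, Mmp9 and S100a8 are genes of neutrophils, whose share was lower at EV-deficient sites.

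Type I interferon genes were higher as a list at EV-deficient sites in all 7 classes with the preset correlation and in 0 with an estimated one. For their mean change the 20 splits of the 8 libraries that keep 1 pool on each side, as the design does, are too few for a share under 0.05 (0.87, against 0.73 in the highest other); of all 35 splits 1, the real one, gave 0.87 and the highest other (EV-deficient 1 with EV-proficient 1, 2 and 3 against the rest) 0.83. As the whole cause, the tables argue against free RNA from interferon-responding cells taken up alike by all droplets. EV-deficient sites held 29.6 more list UMIs per fibroblast but 3.69 per endothelial cell (difference 25.9, SE 7.05). Medians from 0.63 without clusters 13 and 21 (all cells and the 2 classes holding them, leave-one-out SD 0.0822) argue against more such cells. Calls in 7 of 7 classes in the separate libraries alone argue against the 2 pool lanes. What stays open as a hypothesis is that senescent cells that cannot release vesicles may evoke more interferon signalling around them, which was not tested beyond this comparison. Handling also stays open, since immediate-early genes were higher as a list in monocytes/macrophages, dendritic cells, fibroblasts, endothelial cells and pericytes too, though lower in neutrophils (median -0.11, camera Benjamini-Hochberg adjusted p = 0.0285, but 0.14 in the pools alone) and called in none of these with an estimated correlation (adjusted p 0.331 to 0.551).

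The neutrophil share was lower at EV-deficient sites in both batches (difference over the 8 libraries -12.2 points, exact permutation p = 0.05, Benjamini-Hochberg adjusted p = 0.25). The tables argue against a larger recovery of endothelial, epithelial and other non-immune cells as the cause, since among immune cells alone the difference was -15.5 points (exact permutation p = 0.05, adjusted p = 0.1). Recovery of low-RNA barcodes cannot be judged from kept cells: those of at least 500 genes gave -14.2 points (exact permutation p = 0.05, adjusted p = 0.25). Lower recruitment of neutrophils may underlie the difference, but their survival during dissociation was not tested. The difference was not called after adjustment over the classes, which the smallest possible p did not allow.

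Matrix genes were lower in all cells summed (median log2 fold change -0.56) and as a list in neutrophils, monocytes/macrophages and pericytes, but called in none of these with an estimated correlation (camera Benjamini-Hochberg adjusted p 0.331 to 0.389), nor in neutrophils without either pool. An even loss of fibroblasts among the cells would lower other fibroblast genes too, but the median of Dcn, Lum, Dpt and Pdgfra was 0.29, which is 0.85 higher (SE 0.307), although Pdgfra alone was at -0.72. A shift between kinds of fibroblast stays open, as Dcn, Lum and Dpt led cluster 28, with 40.7% of EV-deficient and 20.5% of EV-proficient fibroblasts in the separate libraries, and collagens led cluster 19, with 40.7% and 61.5%. In neutrophils the log2 ratio of Col1a1 to Col3a1 differed from that in fibroblasts by 0.31 (SE 0.255), within the error. Free fibroblast RNA read in neutrophils would give a like ratio, so it stays open. Collagen made by neutrophils is not excluded, as those of the separate libraries held only 4 to 31 UMIs of Col3a1 each. A lower matrix output per fibroblast or pericyte stays open too, which could follow from the vesicle block; within fibroblasts the list had a median of -0.11 and no call.

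For counts of changed genes the 20 splits with 1 pool on each side are too few for a share under 0.05 in neutrophils (140, against 15 in the highest other split; 1 of all 35 splits as large), monocytes/macrophages (338 against 4; 1 of 35) and dendritic cells (29 against 21; 1 of 35), where the real count was 1 at Leiden resolution 2.0. Chance cannot be excluded in all cells summed (39 against 179; 2 of 35, although the highest other within batch called 0 and the split of 179 set both pools on 1 side), fibroblasts (3 against 3; 3 of 35), endothelial cells (13 against 88; 2 of 35) or for the 59 called list pairs (60 in the highest other split; 3 of 35). In epithelial cells the count of 0 is matched by all 35 splits (35 of 35, highest other 77), which tells nothing. In pericytes the 10 splits are too few for a share under 0.05 (21 against 2; 1 of 10). Splits that called several times the real count point to a structure of the samples. In all cells it set EV-deficient 1 and 2 with both pools against the rest, in endothelial cells EV-deficient 1, 2 and pool with EV-proficient 1, and in epithelial cells EV-deficient 1 with the separate EV-proficient libraries.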

How the results depend on the processing

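The 12-tumour fit by hashtag mixture, pool cells with exactly 1 hashtag, shares without unnamed cells, fits without clusters 13 and 21 and the list tests under all but the estimated correlation and the block were chosen after the data were seen; the other alternatives were planned. Of 102 called named genes, 0 reversed in 2259 values under 23 alternatives, 1541 kept their call and 718 lost it with the same direction. Losses were 0 of 102 with RLE size factors, 1 with at least 500 genes, 4 with at most 10% mitochondrial counts and 16 with DESeq2, but 74 of 99 in the separate libraries alone, 84 of 102 without the batch term and 76 and 75 without the EV-deficient or EV-proficient pool. Fits without a library test fewer. Without a pool, the batch term absorbs the other, nearly repeating the separate libraries. Of 59 called list pairs 1005 of 1186 values kept the call, 178 lost it and 3 reversed. Leaving out 1 library ended the call of 23 of the 59, moved the median of 33 by over 1.5 times and turned 1, chemokines in endothelial cells (-0.083). Type I interferon genes were called higher in all cells and each class tested in every setting but the estimated correlation, which called 0 of the 59 pairs. Calls were least likely in epithelial cells and pericytes, where a 2-fold change was recovered for 13.3% and 10.3% of simulated genes; whether depth or spread between libraries sets this was not tested.

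Counts of changed genes in edgeR moved by over 1.5 times as follows; apart from fewer libraries or more genes tested, the cause was not tested. The separate libraries alone gave 0 in all cells (1465 at an unadjusted p under 0.05), 20 in neutrophils, 48 in monocytes/macrophages, 12 in dendritic and 5 in endothelial cells. Without the batch term there were 1 in all cells, 7 in neutrophils and 0 in monocytes/macrophages, dendritic and endothelial cells (807, 619 and 667 unadjusted). The pools alone, 3 against 3 tumours by hashtag with 1 library per group, gave 6386 in all cells, 2419 in neutrophils, 2317 in monocytes/macrophages, 1152 in dendritic, 1685 in epithelial, 107 in fibroblast and 0 in endothelial cells (364 unadjusted); there tumours of 1 lane share its technical effects. The 12 tumours by hashtag mixture gave 3473, 1455, 1821, 491, 50, 36 and 0 (501 unadjusted) in the same order, and the hashtag ratio rule gave 3388 in all cells, 1434 in neutrophils, 1798 in monocytes/macrophages, 465 in dendritic cells, 117 in epithelial cells, 78 in fibroblasts and 47 in pericytes. That rule gave exactly 1 hashtag to 49.2% of EV-deficient and 48.6% of EV-proficient pool barcodes, against 51.3% and 47.6%. Exactly 1 hashtag was on 94.3% of pool cells in monocyte/macrophage cluster 2 but 39.4% in cluster 6, and on 10.2% in epithelial cluster 12 but 74.1% in cluster 36.

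DESeq2 called 741 genes in all cells, 48 in dendritic, 52 in endothelial, 7 in epithelial and 59 in fibroblast cells and 40 in pericytes. With no low-count filter, which tests more genes, edgeR called 230 in all cells, 277 in neutrophils, 820 in monocytes/macrophages, 158 in dendritic, 221 in endothelial, 25 in epithelial and 207 in fibroblast cells and 159 in pericytes. Leiden resolution 2.0 gave 1 in dendritic and 7 in endothelial cells. Doublets kept gave 19 in all cells, and leaving out clusters 13 and 21 gave 23. Pool cells with exactly 1 hashtag gave 0 in endothelial cells (833 unadjusted), 1 in fibroblasts and 53 in pericytes. Leaving out 1 library gave 0 to 252 in all cells, 22 to 131 in neutrophils, 46 to 439 in monocytes/macrophages, 14 to 59 in dendritic cells, 0 to 228 in endothelial cells, 1 to 20 in fibroblasts and 11 to 53 in pericytes, with 0 throughout in epithelial cells and 59 to 72 called list pairs.

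With the replicate number as a block, edgeR called 1 gene in fibroblasts and 0 in pericytes (327 unadjusted), and 30 of 102 named genes and 3 of 59 list pairs lost their call; no other count moved by over 1.5 times, and the block changed no other call of a named gene or a called list pair. The neutrophil share difference under the block stayed at -12.2 points, at p = 0.125, the smallest the exact permutation then allows. The numbers do not pair the samples: deviations of same-numbered separate libraries correlated at -0.0928, 0.0185 and 0.0760 over 15170 genes, and the highest correlation was 0.157, of EV-deficient 1 with EV-proficient 2, so not every library correlated best with its own number.

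The neutrophil share was lower in every setting, by -18.2 to -10.2 points, with exact permutation p = 0.005 and adjusted p = 0.05 over the 12 tumours, a p that takes the 3 tumours of 1 lane as independent, although lane and group are confounded, and uses only pool cells with exactly 1 hashtag. The differences of other shares that reversed, in points, none with a call, were dendritic among immune cells (0.25), erythroid with at least 500 genes per cell (-0.051), and fibroblast in the pools alone (-0.21), under the ratio rule (-0.070) and without unnamed cells (-0.085). Leaving out 1 library gave -1.41 to 0.65 for dendritic, -2.21 to 6.71 for epithelial, -0.0019 to 0.93 for erythroid, -0.13 to 0.46 for fibroblast and -2.15 to 8.07 for monocyte/macrophage cells, and without a reversal 3.72 to 11.4 for endothelial, 0.35 to 1.24 for pericyte, 0.38 to 1.27 for Schwann and 0.45 to 0.93 for T cell/ILC cells. As differences of plain group means, these ranges also hold the changed weight of pools against separate libraries. Other causes were not tested.

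Vesicle genes in epithelial cells, none called in the 8 libraries, reversed most in the pools alone: Cd82 (-0.19), Cttn (-0.13), Hgs (-0.15), Rab31 (-0.10), Rab35 (-0.17), Snap23 (-0.31), Stam (-0.34), Vps4a (-0.16) and Ykt6 (-0.091). With the 12 tumours by mixture Cd82 (-0.010), Snap23 (-0.11) and Stam (-0.13) reversed, and with the ratio rule Snap23 (-0.17) and Stam (-0.13). Pld2 was at -0.13 in the separate libraries alone, -0.013 at resolution 2.0, -0.0075 with RLE size factors, -0.025 without the batch term and -0.0039 with exactly 1 hashtag. Leaving out 1 library gave -0.036 to 0.48 for Cd82, -0.089 to 0.45 for Cd9, -0.12 to 0.40 for Chmp4b, -0.013 to 0.43 for Cttn, -0.19 to 0.26 for Hgs, -0.13 to 0.13 for Pld2, -0.10 to 0.27 for Snap23 and -0.13 to 0.27 for Stam. Of 616 values of 28 of the uncalled named genes 569 kept direction and side, 33 reversed and 14 passed. The 3 reversed lists were endothelial activation in endothelial cells (-0.21) and immediate-early genes in neutrophils (0.14), both in the pools alone, and proliferation in monocytes/macrophages at resolution 2.0 (0.033). The cause was not tested.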

Other observations

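All values here were chosen after the data were seen. Carcinoma cells were sought within the epithelial class by h_dLNGFR, a feature of that name in the deposited gene lists that was most frequent in a few epithelial clusters. The labels do not describe this feature, so that its clusters hold carcinoma cells is an assumption. Clusters 10, 18, 24 and 36, in which at least 50% of cells held a UMI of it, comprised 1457 cells (11.6% of kept cells) in the EV-deficient pool and 354 (3.00%) in the EV-proficient pool, against 1 to 5 cells in each separate library. Clusters 24 and 36 lay almost wholly in the EV-deficient pool, with 226 of 229 and 58 of 58 cells. In these clusters 59.1% of cells (Wilson interval 56.5% to 61.6%) held h_dLNGFR in the EV-deficient pool and 46.3% (41.2% to 51.5%) in the EV-proficient pool, at median depths of 10869 and 115980 UMIs. Neutrophils, which should lack it, held it in 4.51% (3.87% to 5.26%) and 2.13% (1.75% to 2.60%) of cells at median depths of 2357 and 3529 UMIs. Outside these clusters h_dLNGFR was on 19.2% (17.6% to 20.96%) of the other epithelial cells and 37.3% (33.2% to 41.5%) of the unnamed cells of the EV-deficient pool, against 4.52% (3.51% to 5.80%) and 2.91% (2.37% to 3.56%) in the EV-proficient pool, so the clusters need not hold all carcinoma cells. Cells of such depth can be doublets, which were not removed within a tumour. In all cells summed h_dLNGFR had a log2 fold change of 1.65 (edgeR Benjamini-Hochberg adjusted p = 0.0936).

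Because these clusters came from 1 library per group, no test between the groups was made; intervals cover counting error only, and percentiles among random lists describe these 2 libraries and nothing beyond them. Interferon-induced genes such as Bst2 were higher in these clusters in the EV-deficient pool. Bst2 stood at 408 CPM (exact Poisson interval 403 to 413) against 138 (134 to 141), and Isg15 at 196 against 72.1 CPM. The type I interferon list had a median log2 ratio of 1.09 (24 of 28 members higher), the MHC class I list of 0.86 (14 of 15) and the interferon gamma list of 0.92 (12 of 12), each above all 10000 random lists of like size and expression (percentile 100). So were chemokines (0.47, 19 of 23), dendritic cell maturation genes (0.44, 14 of 17) and efferocytosis genes (0.42, 15 of 19), so the shift was not one of interferon genes alone. Class II genes (0.19, percentile 98.4), classical macrophage activation (0.18, percentile 98.6) and NF-kB genes (0.08, percentile 98.6) were high as well, and RNA from monocytes/macrophages, which made up 28.3% of the EV-deficient and 11.2% of the EV-proficient pool, was not excluded. In contrast mitochondrial genes were lower (-0.47, 1 of 13 higher, percentile 0.04). Matrix genes (-0.64, 6 of 23 higher) and keratinocyte differentiation genes (-0.64, 6 of 24 higher) lay below all of them (percentile 0), and proliferation genes were at -0.26 (percentile 1.87). Senescence-associated secretory genes were at 0.16 (percentile 99.99), growth arrest genes at 0.005 (percentile 87.1) and vesicle genes at -0.06 (percentile 59.5), while the median of all 13298 measured genes was -0.11. Rab27a stood at 2.66 CPM (2.28 to 3.08) against 2.85 (2.37 to 3.40), Rab27b at 158 against 153, the senescence marker Cdkn2a at 513 against 407 and Cdkn1a at 174 against 146 CPM. Among genes of at least 50 CPM in either pool, with mitochondrial, ribosomal, sex-linked and Gm or Rik genes left aside, the largest ratio was that of Sprr2f, a cornified envelope gene, at 56.2 against 0.603 CPM, and the smallest was that of the kallikrein Klk10, at 12.6 against 116.7 CPM. Krt6a, a wound keratin, stood at 142 against 763 CPM.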
